A study of Homo sapiens with 3 samples.

How the data were processed

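Transcription start sites (TSSs) were mapped in MCF-7 cells, an established human breast carcinoma line that expresses the estrogen receptor, by 5′-GRO-seq. In this assay nuclei extend their engaged RNA polymerases in the presence of a bromouridine nucleotide, the labelled nascent RNA is captured with an antibody, and enzymes select RNAs whose 5′ end carries a cap, so that the first base of a read marks the start of a transcript. The series holds 3 samples: 1 library made without an RNA fragmentation step, 1 made with it, and 1 conventional GRO-seq control, for which no list was analysed here. Per the labels' protocols, the library with fragmentation was also treated with polynucleotide kinase and with an exonuclease that digests RNA bearing a 5′ monophosphate. The protocol text for the library without fragmentation names neither treatment, so every difference between the lists is a difference between 2 libraries that differ in several steps.

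For each 5′-GRO-seq library the authors deposited 1 list of focused TSSs. Each entry is 1 base with its strand, a score, and a value between 0.67 and 1.00 that follows the letters FI in the entry's name. The score in the deposited lists is a whole number of at least 20. Whether it is a raw or a scaled number of reads, how FI is defined, and which peak caller and limits the authors used are not given in the sources used here, so scores are compared only as ranks and ratios and no count model was fitted. Reads were aligned with Bowtie2 to hg19, per the submitters' processing notes, which give no Bowtie2 version. All positions below are hg19 coordinates, counted from 1.

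No hg19 sequence or annotation was used here. The gene table at hand describes GRCh38, and coordinates were not carried between builds. Several results chosen before the data were examined were therefore not computed: matches to the initiator and to other core promoter motifs, the base composition around the TSS, and the place of TSSs relative to annotated genes. Gene lists fixed in advance (ribosomal proteins, luminal breast genes, immediate early genes, markers of other cell types and others) could not be applied for the same reason, and no gene is named. The rule for named genes would have given up to 4 shared members of each list by rank of the score, up to 6 members of the lists for other cell types, the 5 leading genes over all shared TSSs and the 5 leading genes found in each library only, all within 200 bp of an annotated start. Only its last parts could be used, and for positions instead of genes: the 5 shared positions with the highest smaller-of-the-two rank by score, and for each library the 5 highest-scoring positions with no listed position within 50 bp on the same strand in the other list. Positions named for an extreme ratio, the genomic windows, the distance classes between same-strand neighbours and the set of strongly lower positions were chosen after their values were seen.

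Lists were compared with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. A position was called shared when the identical base on the same strand was in both lists. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat positions as independent. With 1 library per protocol there is no replicate check, and no p-value is given between libraries. The overlap was compared with 100 draws in which every position of the list without fragmentation was moved by a random offset of 200 to 2000 bp. The score ratio at a shared position is the score with fragmentation over the score without it. Ratios were centred on their median, and ratios of list totals served as the alternative scale. Alternatives to these choices (the distance that counts as shared, the strand, the score required, the distance to a partner and the scale of the ratios) are given after the report. Neighbours on the opposite strand were searched up to 500 bp upstream and downstream within the same list, and moved positions (20 draws, offsets of 5000 to 50000 bp) gave the background. A group of shared positions with a centred log2 ratio under -4 was compared with 10000 random lists of the same size drawn from the 7616 shared positions with a centred log2 ratio of at least -1 and matched on the mean log2 score of both libraries in bins of 1. The functions were tested on simulated lists of 13146 positions: 8000 of 8000 planted shared positions, 80 of 80 planted strongly lower positions and 3002 positions against 3000 planted upstream partners were found.

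The depth in reads of either library is unknown from the lists. The scores of the listed positions summed to 4939919 without fragmentation and 3502564 with it. A position scoring under 20, or with FI under 0.67, is in neither list, so absence from a list does not show absence of initiation.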

Results

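The 5′-GRO-seq libraries from MCF-7 cells gave 13146 focused TSSs without RNA fragmentation and 15943 with it. The comparison asks whether focused initiation is found at the same places in both libraries, which differ in fragmentation and in other steps. Below, with and without fragmentation name the libraries and not the effect of that step alone. Both lists covered 23 chromosomes, with no entry on the Y or mitochondrial chromosome. Initiation was close to evenly split between strands: 50.5% of positions (95% interval 49.7 to 51.4) were on the plus strand without fragmentation and 51% (50.2 to 51.8) with it. The median score was 44 without fragmentation (interquartile range 27 to 97) and 45 with it (28 to 99). Median FI was 0.82 and 0.81. The library without fragmentation was more top-heavy: its 10 highest positions held 23.0% of the summed score and its 100 highest held 55.4%, against 11% and 35.6% with fragmentation.

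The same bases were found as focused TSSs in both libraries at 8470 positions. These made up 64.4% of the list without fragmentation (95% interval 63.6 to 65.2) and 53.1% of the list with fragmentation (52.3 to 53.9). When positions were moved by random offsets, the mean number at an identical base was 1.04 and the highest of 100 draws was 4. Displaced matches were rare between 3 and 12 bp. Of the positions without fragmentation, 388 had their nearest same-strand neighbour in the other list at 1 or 2 bp, 4 at 3 to 12 bp and 712 at 13 to 50 bp. Displacement by 1 or 2 bp went both ways: of the 388, 180 lay upstream and 208 downstream in the library with fragmentation. Allowing 50 bp raised the shares to 72.8% and 61.5%, against at most 0.951% in 20 draws with moved positions.

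How often a TSS was found in both libraries rose with its score. In the lowest score decile 37.4% of positions without fragmentation (34.8 to 40.1) and 19.5% with fragmentation (17.6 to 21.5) were shared. In the highest decile the shares were 86% (84.0 to 87.8) and 91% (89.5 to 92.4). Sharing also rose with FI, from 39.5% at FI 0.67 to 0.70 to 75.9% at 0.91 to 0.95 without fragmentation, and from 34.4% to 66.3% with it. Positions with FI of exactly 1 were shared less often, at 51.6% (46.2 to 57) of 347 and 45.3% (40.5 to 50.3) of 419, and had low median scores of 29 and 27. Among positions with a score of at least 100 and FI of at least 0.80, 89.5% of 2189 without fragmentation (88.1 to 90.7) and 94.4% of 2464 with it (93.4 to 95.2) were at identical bases in both lists.

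**Figure D1:**
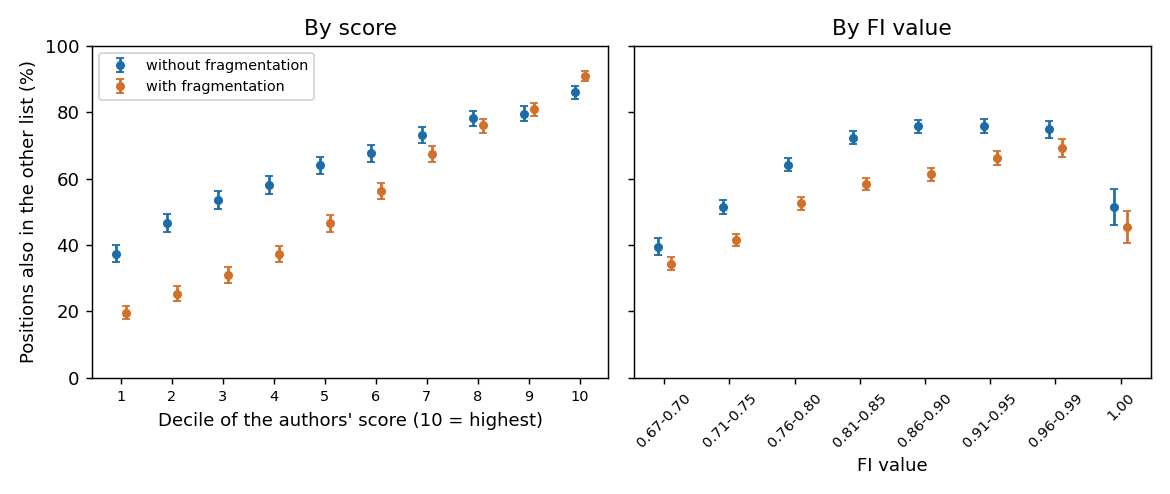
Share of focused TSS positions, in percent, that were at the identical base and strand in the other list, by decile of the authors' score (left) and by FI value (right). Points are shares within 1 library and bars are exact 95% intervals covering counting error only; the share rose from 37.4% to 86% without fragmentation and from 19.5% to 91% with fragmentation across score deciles.

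The 10 highest TSSs of each list were all at bases listed in both libraries, but only 5 were among the 10 highest of both. Of the 10 without fragmentation, 3 fell under a centred log2 ratio of -4. The highest-scoring base of each list was the same, on the minus strand of chromosome 11 at position 62609281, with a score of 487691 without fragmentation and 100461 with it. The other TSSs ranking highest in both lists were on chromosome 14 at 58706689 (minus strand, scores 72434 and 56552), chromosome 15 at 65597015 (plus strand, 188223 and 30922) and at 65588389 (plus strand, 114348 and 26389), and chromosome 1 at 204475649 (plus strand, 44629 and 35240). Their FI was between 0.93 and 1 in both libraries. Across the 8470 shared positions, scores of the libraries correlated with Spearman's rho 0.784 and Pearson's r 0.831 on the log2 scale. These are correlations across positions, which are not independent replicates. FI correlated with rho 0.675, and 60.3% of shared positions had FI values within 0.05 of each other.

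Scores at shared positions were a median 1.25-fold higher with fragmentation, although the summed score of the whole list was 0.709 times that without it. The mean score per listed position was 376 without fragmentation and 219.7 with it. The log2 scales given by the median and by the totals differ by 0.82, so directions below are relative to the median ratio. On that scale 78.0% of shared positions were within 2-fold. Over 4-fold differences were found at 96 positions higher and 189 positions lower with fragmentation. With list totals as the scale the split turned, with 716 higher and 100 lower. The largest relative gain with fragmentation was on chromosome 14 at 90863216 (minus strand), from 96 to 1428, and the next was on chromosome 12 at 96794340 (minus strand), from 183 to 2025. No shared position was over 16-fold higher on the median scale, and 1 was on the scale of list totals.

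At 72 shared TSSs, on 19 chromosomes, scores were far lower with fragmentation, below a centred log2 ratio of -4. Positions lay on both sides of that limit, with 17 from -4 to -3 and 10 from -5 to -4. Counts rose again further down, to 26 from -8 to -7. Limits of -3 and -5 gave 89 and 62 positions. Their median score was 6604.5 without fragmentation (range 274 to 45992) and 62.5 with it (range 20 to 2404). The median fold between the raw scores was 100.65. These positions held 16.2% of the summed score without fragmentation and 0.314% with it. Their FI was high in both libraries, with medians of 0.96 and 0.94. The lowest ratios were on chromosome 11 at 62620865 (minus strand, 24964 against 58), chromosome 17 at 27049602 (plus strand, 18070 against 44) and chromosome 11 at 62623103 (minus strand, 9580 against 24). Chromosome 5 at 180668890 (minus strand, 16361 against 43) and chromosome 3 at 186502587 (plus strand, 37986 against 103) followed. Of the 72, 64 stayed under -4 when list totals set the scale. Both lists start at a score of 20, so only positions well above it without fragmentation could fall under -4. Positions that fell below 20 with fragmentation are not in the set.

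**Figure D2:**
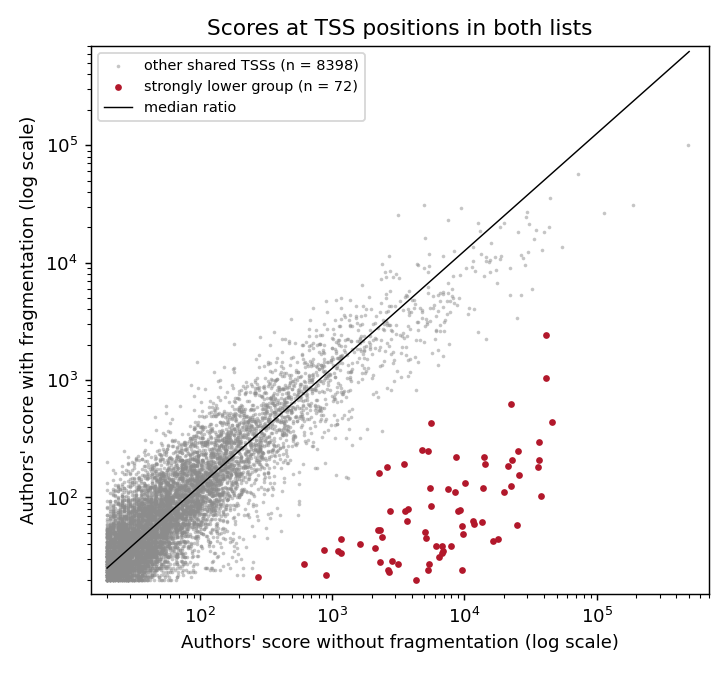
Authors' score of each TSS position found in both lists, without fragmentation (horizontal, log scale) against with fragmentation (vertical, log scale). Each point is 1 of 8470 shared positions in 1 library per protocol. The line is the median ratio of 1.25. The 72 positions of the strongly lower group (red) are those under a centred log2 ratio of -4, a limit with positions on both sides.

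Members of this set lay in short runs on 1 strand. In 13 places 2 to 7 members followed each other with gaps of at most 5000 bp, and 41 of the 72 members were in such runs. The longest runs were 7 members on the minus strand of chromosome 1 between 173833356 and 173836881 and 6 members on the minus strand of chromosome 11 between 62620865 and 62623103. Runs of 4 members each were on the plus strand of chromosome 1 between 45241537 and 45244062 and on the plus strand of chromosome 19 between 49993224 and 49994432. Only 1 of the 72 had a focused TSS on the opposite strand within 500 bp upstream in either list (1.39%, 95% interval 0.0352 to 7.50).

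Positions found in 1 library only had lower median scores and lower median FI than shared ones. Without fragmentation 3572 positions had no listed same-strand TSS within 50 bp in the other list, with a median score of 30 and FI of 0.78, against 56 and 0.84 at shared positions. With fragmentation there were 6132 such positions, with a median score of 30 and FI of 0.79, against 74 and 0.84. The strongest positions listed only without fragmentation were on chromosome 21 at 9827005 (plus strand, score 26768, FI 0.97), chromosome 6 at 27487301 (plus strand, 18426, 0.75) and chromosome 1 at 173834042 (minus strand, 16257, 0.93). Chromosome 17 at 27050703 (plus strand, score 7848, FI 0.99) and chromosome 6 at 133137944 (plus strand, 5401, 0.89) came next. The strongest positions listed only with fragmentation had FI near the lower end of the list. They were on chromosome 17 at 8090904 (plus strand, score 7160, FI 0.69), chromosome 1 at 145395597 (minus strand, 4007, 0.71), chromosome 20 at 25604774 (plus strand, 3041, 0.74), chromosome 20 at 46130680 (plus strand, 2221, 0.72) and chromosome 12 at 51157884 (plus strand, 2112, 0.68). Among list-only positions scoring at least 200, median FI was 0.77 for 202 positions without fragmentation and 0.72 for 141 with it, against 0.89 and 0.87 at shared positions of such scores.

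Focused TSSs were often paired with a TSS that faced away from them, an arrangement known as divergent initiation. Without fragmentation 22.6% of positions (21.9 to 23.3) had a focused TSS on the opposite strand within 500 bp upstream, and with fragmentation 26.5% (25.8 to 27.2). Moved positions gave 0.403% and 0.427% on average. Opposite-strand TSSs within 500 bp downstream were found for 5.89% (5.49 to 6.30) and 6.53% (6.15 to 6.92). The median distance to the upstream partner was 200 bp without fragmentation (interquartile range 130 to 295) and 194 bp with it (126 to 292). TSSs with an upstream partner had slightly lower median FI (0.80 against 0.83 without fragmentation, 0.80 against 0.82 with it) and higher median scores (48 against 43, and 52 against 42).

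**Figure D3:**
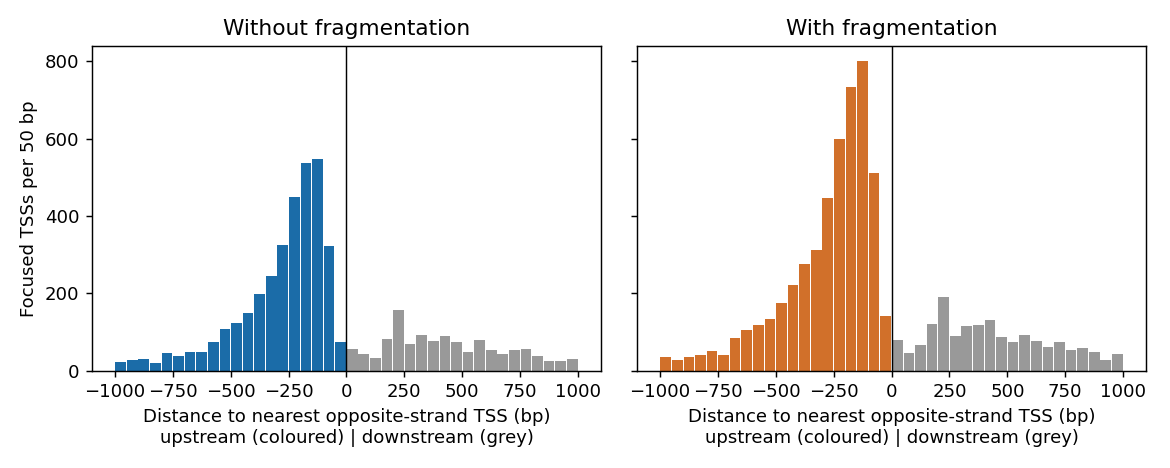
Number of focused TSSs per 50 bp of distance to their nearest opposite-strand focused TSS in the same list, upstream (coloured, negative distances) and downstream (grey), without (left) and with fragmentation (right). Counts upstream peaked at 100 to 149 bp, with 547 and 800 TSSs in that bin.

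Distances between neighbouring listed TSSs on the same strand were uneven. In both libraries 0 pairs of neighbours were 3 to 12 bp apart, while 27 and 38 pairs were 1 or 2 bp apart. On chromosome 1, members of pairs at 1 or 2 bp had equal scores, such as 88 and 88 without fragmentation and 80 and 80 with it. Whether such pairs are separate TSSs or 1 peak listed at tied bases was not tested. The empty range describes the lists, whose peak caller and limits are unknown. It does not show that initiation avoids these distances. From 13 to 27 bp there were 34.4 pairs per bp without fragmentation and 44.5 with it. At 28 to 31 bp these rose to 55.5 and 72.3 pairs per bp, and from 32 to 60 bp they were 15.7 and 23.7. Against the flanking distances of 22 to 26 and 34 to 38 bp, pairs at 28 to 31 bp were 2.14-fold denser in both libraries (95% intervals 1.78 to 2.57 without fragmentation and 1.83 to 2.52 with it). The range of 28 to 31 bp was chosen after these counts were seen, and the flanks leave out the distances next to it. The intervals cover counting error only and do not allow for that choice. Both members were at identical bases in the other list for 46.4% of the pairs at 28 to 31 bp without fragmentation (39.7 to 53.2) and 35.3% with it (29.8 to 41.1). The shares were 41.9% and 32.5% at 13 to 27 bp and 42.5% and 27.7% at 32 to 60 bp.

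**Figure D4:**
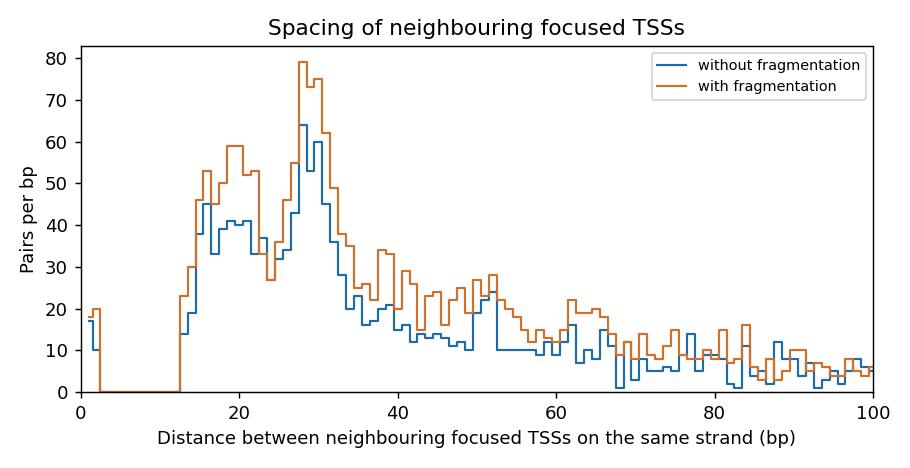
Number of neighbouring focused TSS pairs on the same strand (vertical, pairs per bp) by the distance between them in bp (horizontal), for each library. No pair lay at 3 to 12 bp, and both libraries had their densest stretch at 28 to 31 bp, with 55.5 and 72.3 pairs per bp on average.

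Focused TSSs were spread unevenly over the genome, and alike in both libraries. Per Mb between the first and last listed position, chromosome 19 held 12.3 TSSs without fragmentation and 16.1 with it, chromosome 17 held 9.93 and 12.1, and chromosome 20 held 8.97 and 10.5. Chromosome 18 held 1.25 and 1.65, the fewest in both lists. The densest windows of 1 Mb were on the short arm of chromosome 6, from 26 to 27 Mb (96 positions in each list) and from 27 to 28 Mb (89 and 90). The stretch from 26 to 29 Mb on chromosome 6, where the major cluster of replication-dependent histone genes and many tRNA genes are known to lie, held 250 positions without fragmentation and 258 with it. Median scores there were 299 and 279, against 44 in the rest of each list, and median FI was 0.86 and 0.865 against 0.82 and 0.81. Sharing in this stretch was 75.6% (69.8 to 80.8) and 73.3% (67.4 to 78.6). The highest score decile of each whole list, which holds these median scores, had shares of 86% and 91%. Sharing in the stretch was not compared with that of other positions of like score. Its 189 shared positions had a median centred log2 ratio of -0.44 (interquartile range -1.08 to 0.24), and 0 of them belonged to the strongly lower set. The sign of that median depends on the scale, since list totals shift all ratios up by 0.82.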

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

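The shared percentages rose with the distance allowed and with the score required. Without and with fragmentation they were 65.9% and 54.3% within 1 bp, 67.4% and 55.6% within 5 bp, and 72.8% and 61.5% within 50 bp. They were 68.9% and 57.2% when both lists were limited to scores from their median up, and 70.9% and 58.5% from their upper quartile up. Ignoring the strand left them at 64.4% and 53.1%. The correlation of scores was 0.779 within 5 bp, and 0.798 when the 72 strongly lower positions were left out. Upstream opposite-strand partners were found for 17.2% and 20.3% within 300 bp and 26% and 30.7% within 1000 bp. Scaling by list totals gave 716 positions over 4-fold higher and 100 over 4-fold lower with fragmentation, in place of 96 and 189. It left 64 strongly lower positions, no scaling left 68, and log2 limits of -3 and -5 gave 89 and 62. With those limits 5 and 1 members had an upstream opposite-strand partner. Wider distances raise shares, and another scale shifts all ratios, by construction; the cause of the other changes was not tested. In all, 26 alternatives were computed, of which 8 stayed within the interval or 1.5 times the main value. The alternatives on scaling and on the strongly lower group were chosen after seeing the data, and all others before. Alternatives on the initiator (alone and over background), on the TATA box, TCT, BREu, DPE and GC box, on annotated starts and on gene lists were not run, since they need the hg19 sequence and annotation. No paired analysis was possible because each protocol has 1 library and the labels carry no replicate numbers. No replicate could be left out, so the spread between libraries of 1 protocol is unknown. The minimum score of 20 limits what the lists can show at weak TSSs.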

Other observations

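Among the densest windows outside chromosome 6, those on chromosome 20 had median scores near those of the whole lists. Of the tests given in this part, those on upstream partners and on pairs across lists were set before their results were seen, and those on compression, the exonuclease step and the limits of the lists were chosen afterwards. On chromosome 20 the window from 46 to 47 Mb held 65 TSSs without fragmentation and 79 with it, with median scores of 41 and 37, and the window from 52 to 53 Mb held 67 and 62, with median scores of 36 and 41.5. The window from 57 to 58 Mb on chromosome 17 held 48 and 49 TSSs with median scores of 69 and 55, and that from 21 to 22 Mb on chromosome 14 held 46 in each list with median scores of 124.5 and 113. Upstream opposite-strand partners differed between dense regions. They were found for 52.1% and 51% of the TSSs in the chromosome 17 window, 46.9% and 52.7% from 151 to 152 Mb on chromosome 1, 29.9% and 25.8% from 52 to 53 Mb on chromosome 20, and 15.6% and 19% from 26 to 29 Mb on chromosome 6. Opposite-strand TSSs downstream, which face the first TSS, were most numerous at 200 to 249 bp among 50 bp bins up to 999 bp. That bin held 156 TSSs without fragmentation and 190 with it, against 81 and 120 at 150 to 199 bp and 68 and 90 at 250 to 299 bp.

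The first pattern is the set of 72 shared positions with scores far lower with fragmentation. Whether compression of high scores is a part of the cause was not settled. Of all 219 shared positions scoring at least 2819 without fragmentation, the lower quartile of the set, 54 were under -4 (24.7%, 95% interval 19.1 to 30.9). Most shared positions at such scores were therefore not under -4, which argues against compression acting by score alone as the whole cause. Compression as the whole cause was taken to need over 50%, a bound set after the counts were known. The 54 follow from the choice of floor, and positions missing from the list with fragmentation were not counted. The 219 positions, members of the set included, had a median centred log2 ratio of -1.31 (interquartile range -3.12 to -0.62). Picking positions by a high score without fragmentation favours low ratios, so this median does not measure compression. Compression stays open as a part of the difference. The hypothesis that these are RNA 5′ ends made by processing, such as small nucleolar RNAs cut from introns of host genes, predicted few upstream partners: 1 of 72 had one, against a mean of 28.7 and a lowest value of 14 in 10000 matched lists. Another same-strand TSS within 5000 bp was near 63 of the 72, against a mean of 33.6 and a highest value of 50. With members of the set not counted as neighbours, 61 of the 72 had one, against a mean of 33.2 and a highest value of 50. Neighbours were sought in the list without fragmentation, so positions listed only there were still counted. Of 38 such positions scoring at least 1000, 18 lay within 5000 bp of a member. The count may thus partly reflect the runs of the set itself. The matched lists shared the mean log2 score of both libraries and held only positions with a centred log2 ratio of at least -1. Their positions therefore scored lower without fragmentation than the set. Few partners and near neighbours go with processed ends, but part of the contrast may come from this matching. The RNA class was not identified without an hg19 annotation. Whether the exonuclease step itself, rather than fragmentation, the kinase step or 1 unusual library, lowered these scores cannot be told apart with 1 library per protocol, and the design names no biological difference to set against it.

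The second pattern is the positions listed in 1 library only. The lower limits of the lists may account for most of those with fragmentation, because 97.8% of positions with a score of at least 100 and FI of at least 0.80 had a partner within 50 bp (95% interval 97.1 to 98.3). Without fragmentation the corresponding share was 92.4% (91.2 to 93.5). By this measure the limits may account for most list-only positions without fragmentation as well. A second measure, applied only without fragmentation, took the 38 list-only positions that scored at least 1000. The limits as the whole cause were taken to need a median FI under 0.80 for these, a bound chosen afterwards. Their median FI without fragmentation was 0.865 (interval of the median 0.80 to 0.94, touching the bound). Of the 38, 26 had FI of at least 0.80. The score limit would hide these 38 only after a fall of over 50-fold, itself a loss. A fall of FI under 0.67 stays open, as their FI in the other library is not listed, so this measure does not decide. Of those 38, 18 lay within 5000 bp of a strongly lower position on the same strand, against 0 of 13 with fragmentation.

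The third pattern is the excess of same-strand pairs 28 to 31 bp apart. If exclusion of close neighbours within each list alone made it, pairs with 1 member in each list and neither position in both should lack it. Such pairs were 2.12-fold denser at 28 to 31 bp than at flanking distances (56 against 66 pairs, 95% interval 1.46 to 3.08). The excess was thus not limited to pairs within 1 list. Between the lists, however, 4 positions without fragmentation had their nearest neighbour at 3 to 12 bp, against 712 at 13 to 50 bp. A selection by the peak calling that acts alike in both libraries would reach such pairs too, so the test cannot decide on it. The cause of the empty range from 3 to 12 bp was not tested. The upstream member had the higher score in 110 of 222 pairs without fragmentation and 130 of 289 with it. No biological explanation was tested, and the sequence between the members was not analysed here.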
